A study of Mus musculus with 12 samples.

How the data were processed

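Single-cell RNA sequencing was done on the cerebral cortex of 12 C57BL/6 mice, 1 library per animal, in 4 groups of 3. Per the labels' protocols, mice received a controlled cortical impact, in which a piston strikes the exposed cortex, or sham surgery without craniotomy or impact. From 30 min after surgery the brain was held for 2 h at 33 °C (hypothermia) or at 37 °C (normothermia). At 24 h the animals were perfused, the cortex on the side of surgery was dissected and digested with enzymes at 37 °C, and myelin was removed with magnetic beads. Droplet 3′ libraries with unique molecular identifiers (UMIs), which count captured molecules, were then made on the 10x Chromium platform. Per the submitters' processing notes, Cell Ranger 4.0.0 and Seurat (version not given) were used with genome build mm10. The aligner's annotation and the filter on cells are not given in the sources used here.

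The deposited matrix holds whole-number UMI counts per gene and cell, not normalized, for 88200 cells and 32285 genes. The cell names carry the library's title, which placed every cell in its library. The smallest count per cell was 1611 UMIs and the largest mitochondrial share 25.0%, so low cells had been removed before deposit. Pairs of libraries shared a median of 0.219% and at most 0.768% of the barcodes of the smaller library.

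Doublets were scored in each library with a nearest-neighbour score against simulated doublets, and 840 cells (0.95%) with a score above 0.15 were called doublets. The labels do not say that doublets were removed earlier. The loading rate gives about 0.8% doublets per 1000 cells, and the score found 42.9% to 64.2% of the simulated doublets per library, except in the library of 912 cells, where it found 0, so doublets remain among the kept cells. All 88200 cells were clustered on 2000 variable genes and 30 principal components with 20 nearest neighbours and the Leiden method at resolution 1 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9), without batch integration, and the called doublets were left out after clustering, which left 87360 cells. Of 46 clusters, 37 were named as classes of "-like" cells from 19 fixed marker lists. A name needed at least 3 markers detected in 25% of the cluster's cells, a marker score of 0.15, no other class at 0.6 times that score or more, and 100 cells. The doublet score limit and these naming limits were set after the clusters had been seen. The 9 clusters without a name held 1161 cells, 0.230% to 1.31% of each sham library, 0.580% to 0.932% of the injured hypothermic libraries, and 4.33%, 1.58% and 3.73% of injured normothermic libraries 1, 2 and 3.

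Cells are not replicates, so counts were summed per animal and class, and the sums were tested across animals. An animal entered a class with 20 or more cells, and a contrast needed 2 or more animals per group. Genes were tested with edgeR 4.0.16 (R 4.3.3): default low-count filter, TMM normalization, a means model over all 4 groups, the quasi-likelihood F test, and Benjamini-Hochberg adjustment at 0.05 over all genes of a class and contrast. The standard error (SE) of a log2 fold change is its size divided by the square root of F. Levels are CPM, counts scaled to a common library total, with the SD over animals, and n is the number of animals. The 5 contrasts were injury at normothermia, cooling after injury, cooling after sham surgery, injury at hypothermia, and the interaction, which is the difference between the 2 injury effects. Microglia-like, astrocyte-like and endothelial-like cells, the 3 largest classes, were analysed in full. Tables were handled with dplyr 1.1.4 and version 1.17.8 of the data.table package, and figures were drawn with matplotlib 3.10.9.

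The 24 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with the correlation estimated from the data, and with fry, adjusted over the lists of a class and contrast. Values of fry in the paired model changed with the settings of the linear algebra library, and no value of fry is printed. Camera asks whether a list's genes moved relative to all other genes. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. The genes named were chosen by a fixed rule. In each class and contrast these were genes past the threshold whose animals did not overlap between the 2 groups and whose higher group averaged 20 CPM or more, the 5 with the largest rise and the 5 with the largest fall, or 2 and 2 in the smaller classes. Markers of other classes, unnamed gene models, ribosomal protein genes and mitochondrial genes were passed over in that choice. Up to 4 members of smallest p were named per list. Where no gene passed in astrocyte-like or endothelial-like cells, and in microglia-like cells with cooling after injury, the 3 genes of smallest p were given. Cirbp and Rbm3 were given for cooling after injury, and in microglia-like cells after sham surgery.

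The share of each class among an animal's kept cells was tested with edgeR on cell numbers, with an exact two-sided permutation test beside it. With 3 against 3 animals that test cannot give a p below 0.1. The share of endothelial-like cells with 3 or more of 16 tip cell markers was taken after thinning each cell to 3000 UMIs. The fold against a group with 0 counts of a gene was computed against a floor of 3 counts over the group, and ratios over 1 to 3 counts carry a 95% interval that covers counting error only.

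Groups share replicate numbers, so pairing was checked from the correlation of same-numbered libraries' deviations from their group means, over genes. Among injured animals every same-numbered pair correlated above 0.1 in all 3 classes: 0.233 to 0.638 in astrocyte-like, 0.12 to 0.69 in endothelial-like and 0.122 to 0.713 in microglia-like cells, against means of −0.235, −0.197 and −0.191 for different numbers. The means for different numbers add no evidence, since deviations from a group mean cancel within the group. Single pairs with different numbers reached 0.124, 0.307 and 0.298 in these classes. In endothelial-like and microglia-like cells that lay above the lowest same-numbered pair. The numbers were taken to pair the injured animals, from the data and not from the labels, which remains an assumption. Same-numbered sham animals had means of 0.197 to 0.282 but missed 0.1 in some pairs. Their lowest values were 0.0925 in endothelial-like, 0.00424 in microglia-like and −0.00641 in astrocyte-like cells. Same-numbered sham and injured animals had means of −0.0366 to −0.0429. A model with a block per number within injured and within sham animals was added after this was seen, and its values are called paired.

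The groups, contrasts, tests, lists, markers, the rule for named genes and the following alternatives were fixed before the data were examined: other size factors in edgeR, DESeq2 1.42.0, no low-count filter, leaving out each animal, the replicate number as a block, only the groups of a contrast, doublets kept, a stricter cell filter (at least 1000 UMIs and at most 10% mitochondrial counts), leaving out markers of other classes, Leiden resolution 0.5, other denominators and sizes for shares, 2 or 4 tip markers, and no thinning.

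The gene tests were tested on simulated data with 200 genes changed. For injury at normothermia, 60% of genes changed 2-fold and 95% of those changed 4-fold were recovered among 14405 genes in microglia-like cells, 30% and 96% among 14933 in astrocyte-like cells, and 39% and 93% among 13558 in endothelial-like cells. Cooling after injury gave 61% and 96%, 37% and 96%, and 47% and 94%. In the paired model it gave 44% and 96%, 15% and 93%, and 16% and 90%. These rates are the simulation's and do not rank the models on the real data.

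Single-cell counts from 3′ ends do not separate a gene from an overlapping or near-identical copy. Classes with too few cells per animal, unnamed clusters, splicing, velocity and trajectories were not analysed here. Coordinates are 1-based on GRCm38 (mm10) with the GENCODE M21 annotation, which was matched by gene symbol.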

Results

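Gene expression was measured in single cells of the mouse cerebral cortex 24 h after a brain injury. The labels place the study within research on therapeutic hypothermia, the cooling of the brain after trauma. The 12 libraries, 1 per C57BL/6 mouse labelled male, formed 4 groups of 3 animals: sham surgery or controlled cortical impact, each followed by 2 h with the brain at 37 °C (normothermic) or at 33 °C (called cooled here). The normothermic sham libraries 1, 2 and 3 held 8254, 9367 and 8323 cells and 67267990, 78713199 and 71708623 UMIs. The cooled sham libraries held 5701, 8245 and 912 cells and 59306499, 77904621 and 11661438 UMIs, so that replicate 3 of this group had 230 microglia-like, 292 astrocyte-like and 235 endothelial-like cells. The normothermic injured libraries held 8385, 8710 and 6511 cells and 100406878, 111950178 and 82064650 UMIs, and the cooled injured libraries 7934, 8205 and 7653 cells and 89234402, 86229962 and 80543448 UMIs. The median cell had 6870 to 10447.5 UMIs per library. Cooled sham replicate 1 stood apart in sex-linked genes: its microglia-like cells had 1163 CPM of Xist, the RNA that silences an X chromosome in female cells, and 1 UMI of 4 Y-linked genes, whereas the other libraries had at most 1.31 CPM of Xist and 405 to 5819 such UMIs.

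Microglia-like cells made up 33.5% of the 87360 kept cells, astrocyte-like cells 24.95% and endothelial-like cells 19.92%. Smaller classes were neuron-like (5.17%), neuroblast-like (3.56%), pericyte-like (2.69%), ependymal-like (1.79%), oligodendrocyte precursor-like (1.63%) and choroid plexus-like cells (1.62%). Monocyte/macrophage-like (887 cells), smooth muscle-like (799), neutrophil-like (622), border macrophage-like (618) and fibroblast-like cells (408) were also named. Values below are means ± SD over n = 3 animals per group unless another n is given, and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

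The first comparison, normothermic injured against sham animals, asks what craniotomy and impact did together, as sham surgery had neither. Blood-borne immune cells were more frequent after injury. Neutrophil-like cells rose from 0.0496% ± 0.0227 to 2.15% ± 1.60 of an animal's cells (log2 5.38, adjusted p = 0.000207), and monocyte/macrophage-like cells from 0.0687% ± 0.0503 to 2.13% ± 1.14 (log2 4.91, adjusted p = 0.000289). The exact two-sided permutation p was 0.1 for both, the smallest that 3 against 3 animals can give. Astrocyte-like cells stood at 32.2% ± 6.15 and 16.7% ± 5.29 (adjusted p = 0.149), and microglia-like cells at 31.1% ± 3.90 and 34.4% ± 2.91. Fibroblast-like cells (0.146% and 0.835%, adjusted p = 0.0727) and choroid plexus-like cells (0.0243% and 4.26%, adjusted p = 0.0579) did not pass. Of the classes, 2 passed here, against 4 with doublets kept and 4 at Leiden resolution 0.5.

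**Figure D1:**
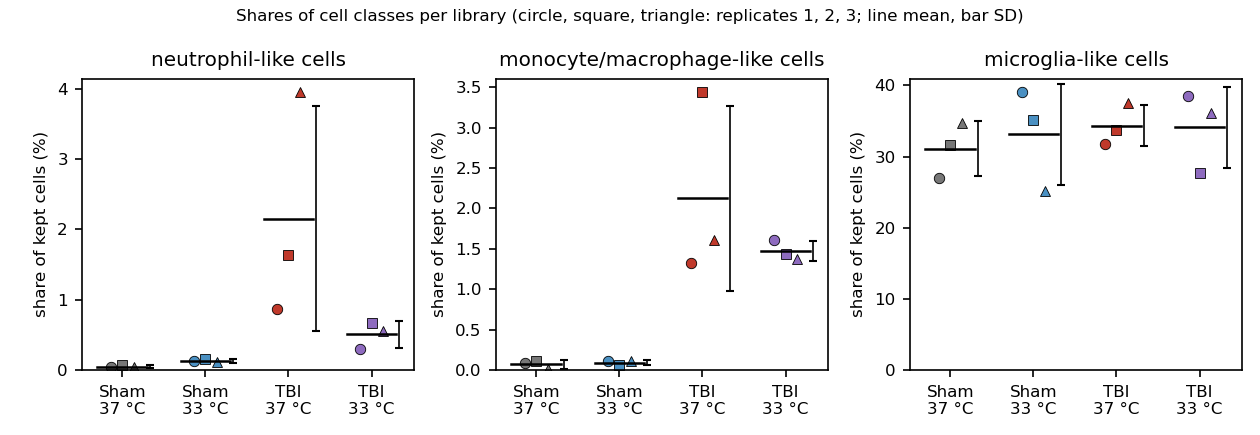
Share of neutrophil-like, monocyte/macrophage-like and microglia-like cells among all kept cells of each library, in percent, by group (circle, square and triangle are replicates 1, 2 and 3, the line is the mean and the bar the SD).

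In microglia-like cells 2388 of 14652 genes changed, 1433 upward and 955 downward. Spp1, which encodes the secreted matrix protein osteopontin, rose from 3.01 ± 2.02 to 1045 ± 566 CPM (log2 8.46, SE 0.78, adjusted p = 0.000123). Adam8, a membrane metalloprotease, rose from 0.508 ± 0.109 to 229 ± 133 CPM (log2 8.80, SE 0.60, adjusted p = 1.95e-05). Il1r2, the decoy receptor of interleukin 1, rose from 0.306 ± 0.202 to 172 ± 269 CPM (log2 9.05, SE 2.15, adjusted p = 0.0156), and Saa3, an acute-phase serum amyloid A, from 0.298 ± 0.0549 to 65.3 ± 101 CPM (log2 7.72, SE 1.54, adjusted p = 0.00754). Cxcl3, a chemokine that attracts neutrophils, rose to 40.0 ± 58.7 CPM over 1 UMI in the sham group, a ratio of 1810 with a counting interval of 324 to 71500 (adjusted p = 0.0119). These 3 genes differed widely between the injured libraries, with 2.89, 9.51 and 86.4 CPM of Cxcl3 and 35.2, 0.896 and 387 CPM of Il1r2 in replicates 1, 2 and 3. The neutrophil gene S100a8 stood at 11.2, 6.61 and 33.1 CPM in the same cells. P2ry12, the ADP receptor of homeostatic microglia, fell from 2057 ± 571 to 444 ± 237 CPM (log2 −2.21, SE 0.45, adjusted p = 0.00804). Among the deepest falls were those in Upk1b (31.7 ± 19.5 to 2.93 ± 1.69 CPM), in Tnfrsf17, a receptor for the B cell factors BAFF and APRIL (30.5 ± 16.4 to 2.95 ± 2.74), and in Il7r, the interleukin 7 receptor (42.9 ± 20.4 to 7.32 ± 2.41). Lst1 fell from 184 ± 60.5 to 32.1 ± 19.5 CPM and Kcnk12, a potassium channel, from 35.2 ± 8.42 to 6.73 ± 4.78 CPM, with log2 changes over these 5 genes from −3.40 (Upk1b) to −2.37 (Kcnk12).

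Among the fixed gene groups, 5 of 12 measured homeostatic microglia genes fell (10 adjusted over the list alone), including P2ry12 and Siglech, a surface lectin (log2 −1.70, SE 0.33, adjusted p = 0.00653). The list was lower than other genes (camera adjusted p = 9.98e-06, adjusted p = 0.366 with an estimated correlation). Of 15 disease-associated microglia genes 8 rose (8 adjusted over the list alone): beside Spp1 these included Lgals3, which encodes galectin-3 (log2 5.71, SE 0.72), the cystatin Cst7 (log2 2.16, SE 0.30) and the lysosomal tetraspanin Cd63 (log2 1.95, SE 0.29). The list's adjusted p was 1.17e-05, and the adjusted p = 0.194 with an estimated correlation. Of 16 cytokines and chemokines 10 rose (12 adjusted over the list alone), with Ccl7 at log2 6.28 (SE 0.66), Cxcl1 at 7.49 (SE 1.11) and Il1rn, the interleukin 1 receptor antagonist, at 5.62 (SE 0.89). This list's adjusted p was 3.17e-08, with adjusted p = 0.198 with an estimated correlation. Of 17 hypoxia and glycolysis genes 9 rose (10 adjusted over the list alone), among them the glycolytic enzymes Pkm (log2 2.63, SE 0.32), Pgk1 (2.04, SE 0.32) and Ldha (1.67, SE 0.28). The list's adjusted p was 9.98e-06, and adjusted p = 0.366 with an estimated correlation. In the oxidative stress and iron list 8 of 14 genes rose and 1 fell (10 adjusted over the list alone). Srxn1 (log2 3.37, SE 0.54) and the haem oxygenase Hmox1 (2.07, SE 0.39) rose, whereas the iron exporter Slc40a1 fell (log2 −1.50, SE 0.30). Its adjusted p was 0.000569, and adjusted p = 0.366 with an estimated correlation.

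The reactive astrocyte list also moved in microglia-like cells: 7 of 11 measured members rose (8 adjusted over the list alone, camera adjusted p = 7.04e-07), and the call held with an estimated correlation (adjusted p = 0.0147). Among these were Cd44, a hyaluronan receptor (log2 5.17, SE 0.50), the intermediate filament genes Vim (5.07, SE 0.49) and Nes (2.53, SE 0.44), and Timp1, an inhibitor of metalloproteases, which had a ratio of 67.4 over few sham UMIs (counting interval 18.4 to 560). Of the A2-type astrocyte list 8 of 10 members rose (9 adjusted over the list alone), led by Emp1 (log2 6.89, SE 0.96) and Ptgs2 (5.04, SE 0.87). Its adjusted p was 9.98e-06, and adjusted p = 0.21 with an estimated correlation. Of the endothelial activation list 4 of 10 rose (4 adjusted over the list alone): the oxysterol enzyme Ch25h (log2 6.41, SE 0.99), the siderophore-binding Lcn2 (5.69, SE 1.06), Ctla2a (3.12, SE 0.59) and Lrg1 (4.90, SE 1.05). Its adjusted p was 0.00127, and adjusted p = 0.104 with an estimated correlation. In the extracellular matrix list 4 of 10 rose and 1 fell (5 adjusted over the list alone), with rises in Fn1, which encodes fibronectin (log2 3.28, SE 0.39), and Postn (adjusted p = 0.00334). Its adjusted p was 0.013, and adjusted p = 0.278 with an estimated correlation. The interferon response list (3 of 15 rose, 4 adjusted over the list alone), the cell cycle list (2 of 16 and 2) and the cholesterol synthesis list (1 of 17 and 6) were called with adjusted p of 0.0184, 0.00511 and 0.00511. With an estimated correlation these were 0.552, 0.504 and 0.198. The inflammasome list was not called and differed in sign between its median (log2 −0.16) and its mean (0.20). Lists with such differences were not called in any comparison.

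Sham microglia-like cells lay mostly in clusters 0 (64.5% ± 19.3, led by P2ry12, marker score 0.973) and 6 (26.5%). Those of normothermic injured animals lay in 7 (25.3% ± 38.3), 14 (25.1% ± 42.5, and 74.2% in replicate 3), 13 (14.8%) and 8 (12.0%). Scores were 0.221 in 14, led by Il1r2, and 0.195 in 13, led by Adam8. Blood-borne macrophages or a changed cluster mix were not excluded. The gene count was 645 without normothermic sham replicate 3, 1341 without sham replicate 1 and 716 with only the groups of the contrast. Without sham replicate 3 the adjusted p of Cxcl3 was 0.0779 (6.71e-06 to 0.0779 over its alternatives). For Il1r2 it was 0.0583, 0.0524 and 0.0739 without sham replicate 1, 2 and 3 and 0.0517 with only the contrast's groups (1.07e-06 to 0.0739), and for Kcnk12 0.0552 with the latter (4.04e-05 to 0.0552).

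Astrocyte-like cells changed in 1265 of 15107 genes, 889 upward and 376 downward. Tgm1, a transglutaminase that cross-links proteins, rose to 66.8 ± 7.22 CPM, a ratio of 2430 (counting interval 671 to 20100) over the few UMIs of the sham group, with an adjusted p = 1.34e-05. Fosl1, a subunit of the AP-1 transcription factor, reached 51.3 ± 71.9 CPM (ratio 3270, counting interval 586 to 129000, adjusted p = 0.00733), and the metalloreductase gene Steap4 24.4 ± 26.6 CPM (ratio 1300, counting interval 232 to 51300, adjusted p = 0.00268). The sphingosine kinase gene Sphk1 reached 42.3 ± 53.7 CPM (ratio 915, counting interval 312 to 4440, adjusted p = 0.00117). The transporter gene Slc10a6, with 0 UMIs in the sham group, was at least 457-fold higher at 21.9 ± 24.0 CPM (adjusted p = 0.00685). The largest falls were smaller. Hapln1, a link protein of hyaluronan and proteoglycans, fell from 202 ± 36.4 to 63.9 ± 3.94 CPM (log2 −1.66, SE 0.17, adjusted p = 0.000351), Arhgap24 from 26.9 ± 3.53 to 8.69 ± 4.65 CPM and Nat1 from 29.1 ± 3.66 to 9.35 ± 5.86 CPM. Nat8f5 and Hist1h4i fell to 11.8 ± 8.61 and 10.7 ± 7.11 CPM, with adjusted p over these last 4 genes of 0.0164 to 0.0316.

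Each of the 13 reactive astrocyte genes rose (13 adjusted over the list alone): examples were the sphingosine phosphate receptor S1pr3 (log2 5.53, SE 0.48), Cd44 (4.00, SE 0.40), Aspg (3.25, SE 0.37) and Timp1 (8.77, SE 0.94). The list's adjusted p was 1.94e-19, and 0.00138 with an estimated correlation. Each of the 12 A2-type genes rose as well (12 adjusted over the list alone), including Ptx3, which encodes pentraxin 3 (log2 7.40, SE 0.64), the cytokine gene Clcf1 (5.58, SE 0.68) and Emp1 (6.97, SE 0.88), with an adjusted p of 1.39e-19 and 0.00214 with an estimated correlation. Of the 11 A1-type genes 10 rose (10 adjusted over the list alone), such as the guanylate-binding protein gene Gbp2 (log2 5.66, SE 0.69), Ggta1 (2.86, SE 0.39) and Srgn (3.08, SE 0.46). Its adjusted p was 3.23e-12, and 0.0345 with an estimated correlation. Of 15 interferon response genes 13 rose (14 adjusted over the list alone), among them Usp18 (log2 3.13, SE 0.49), Oasl2 (3.58, SE 0.59) and Ifit1 (4.17, SE 0.72). Of 15 cytokines and chemokines 14 rose (15), among them Ccl2 (7.47, SE 0.87) and Cxcl1 (6.65, SE 0.97). Both had an adjusted p of 1.19e-13, which with an estimated correlation was 0.0453 for interferon response and 0.0224 for cytokines. In the antigen presentation list 8 of 12 rose (9 adjusted over the list alone), such as H2-D1 (log2 2.32, SE 0.35) and the immunoproteasome gene Psmb8 (adjusted p = 0.00527), with an adjusted p of 3.81e-08 and 0.0394 with an estimated correlation. Of the endothelial activation list 8 of 10 rose (9): the interleukin 1 receptor gene Il1r1 (log2 2.78, SE 0.23), Lcn2 (8.57, SE 1.01), the adhesion molecule gene Icam1 (4.10, SE 0.49) and Lrg1 (7.57, SE 1.30). Its adjusted p was 1.71e-08, and 0.0157 with an estimated correlation.

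Further lists were called in astrocyte-like cells at the preset correlation and not with an estimated one. In the complement list 6 of 10 rose (10 adjusted over the list alone), with the anaphylatoxin receptor gene C5ar1 at log2 3.86 (SE 0.55), and adjusted p = 0.096 with an estimated correlation. In the immediate early and dissociation list 8 of 16 rose (12), with Ier3 at log2 5.12 (SE 0.55) and adjusted p = 0.242 with an estimated correlation. Of the disease-associated microglia list 4 of 13 rose (7), with Spp1 at log2 5.14 (SE 0.54) and Lgals3 at 2.95 (SE 0.52), and adjusted p = 0.0703 with an estimated correlation. The inflammasome (2 of 9 rose and 1 fell), oxidative stress and iron (2 of 14 rose, with Hmox1 at log2 5.91, SE 0.48), heat shock (2 of 12, with Hspa1a at 2.08, SE 0.34) and neurotrophic factor lists (5 of 21) had estimated-correlation values of adjusted p = 0.0525, adjusted p = 0.267, adjusted p = 0.421 and adjusted p = 0.242. Members adjusted over the list alone were 8, 6, 5 and 11. The endothelial tip cell (3 of 14 rose, 7 adjusted over the list alone), extracellular matrix (1 of 10 and 3) and cell cycle lists gave adjusted p = 0.0584, adjusted p = 0.0703 and adjusted p = 0.24 with an estimated correlation.

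Sham astrocyte-like cells lay mostly in clusters 2 (62.4% ± 18.0) and 5 (25.7%), and those of normothermic injured animals in clusters 3 (27.1% ± 40.3, led by Lif, Ptx3 and Fosl1), 15 (18.4% ± 2.21, led by Ptx3, Tgm1 and Gfap), 20 (18.1% ± 20.3) and 2 (15.7%). The gene count was 647, 228 and 247 without sham replicate 1, 2 and 3, 770 without injured replicate 3, 267 with only the groups of the contrast and 2194 by DESeq2. Without sham replicate 2 the adjusted p of Fosl1 was 0.0653 (5.11e-08 to 0.0653 over its alternatives), and the calls of Arhgap24, Nat1, Nat8f5 and Hist1h4i ended without sham replicate 2 or 3 (0.0653 to 0.129), without sham replicate 1 for Nat1 (0.0511) and without injured replicate 2 or 3 for Nat8f5 and Hist1h4i (0.059 to 0.0723), over alternatives that ranged from 0.00018 to 0.129.

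Endothelial-like cells changed in 207 of 13778 genes, 162 upward and 45 downward. The ligand gene Angpt2, which destabilises vessels, rose by log2 3.88 (SE 0.27, adjusted p = 0.000164). Pgf, the placental growth factor, rose from 0.791 ± 0.907 to 159 ± 169 CPM (log2 7.69, SE 1.12, adjusted p = 0.0186), and Apln, the angiogenic peptide apelin, from 8.61 ± 12.6 to 303 ± 225 CPM (log2 5.14, SE 1.07, adjusted p = 0.0453). AA467197 (135 ± 119 CPM), the chemokine gene Ccl2 (48.7 ± 57.3), Saa3 (52.4 ± 77.4) and Sphk1 (30.4 ± 47.3) rose from sham levels under 1 CPM, with log2 changes of 7.86, 7.54, 8.15 and 8.44. Isg15, an interferon-induced ubiquitin-like protein, fell from 329 ± 38.2 to 113 ± 47.4 CPM (log2 −1.55, SE 0.26, adjusted p = 0.0294). Lmntd1, the transcription factor gene Tcf15, Plekhh2 and the serine protease gene Klk8 fell by log2 −2.16, −1.91, −1.86 and −1.76.

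Of the 16 endothelial tip cell genes 4 rose (9 adjusted over the list alone), namely Angpt2, Pgf, Apln and the vasodilator peptide gene Adm (log2 3.72, SE 0.70, adjusted p = 0.0386), with a list adjusted p of 1.02e-10 and adjusted p = 0.0912 with an estimated correlation. Of 15 cytokines and chemokines 4 rose (11), including Ccl7 (ratio 169, counting interval 29.8 to 6740) and Il1b (log2 4.42, SE 0.74), with adjusted p = 0.125 with an estimated correlation. In the A2-type list 4 of 10 rose (6), with Emp1 at log2 4.49 (SE 0.84), and in the hypoxia and glycolysis list 3 of 16 (7), with Pgk1 at 1.63 (SE 0.30). Their estimated-correlation values were adjusted p = 0.0912 and adjusted p = 0.161. The disease-associated microglia list (3 of 11 rose, 7 adjusted over the list alone, with Lgals3 at log2 4.31, SE 0.65), the complement list (1 of 10 and 6) and the reactive astrocyte list (1 of 12 and 7, with Cd44 at 4.18, SE 0.83) each had an adjusted p = 0.0912 with an estimated correlation. The interferon response list was lower, with 1 of 15 members past the threshold (Isg15) and 9 adjusted over the list alone, an adjusted p of 0.000299 and adjusted p = 0.283 with an estimated correlation. The endothelial activation, cold-inducible and extracellular matrix lists, none of whose members passed over all genes (3, 3 and 4 adjusted over the list alone), were higher at the preset correlation, as were the cholesterol synthesis and the oxidative stress and iron lists. With an estimated correlation these gave adjusted p of 0.161, 0.161, 0.234, 0.556 and 0.161.

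Sham endothelial-like cells lay mostly in clusters 1 (76.1%) and 9 (17.1%), and those of normothermic injured animals in 17 (36.0% ± 50.2, and 93.7% in 1 library, led by Ctla2a, Stc1 and Apln), 4 (26.8%) and 1 (24.6%). The gene count was 4, 2 and 1 without sham replicate 1, 2 and 3, and 768 and 93 without injured replicate 1 and 3. It was 72 with the replicate block, 0 with only the groups of the contrast (edgeR, 2700 genes at an unadjusted p under 0.05 over all groups) and 1053 by DESeq2. Among the endothelial genes named, Angpt2 lost its call only with the contrast's groups alone (adjusted p = 0.0517, 6.56e-40 to 0.0517 over its alternatives). The calls of the others ended without each of the 3 sham replicates (Apln without sham replicate 2 or 3 and injured replicate 2 or 3), and their highest values lay between 0.137 (AA467197, from 4.8e-09) and 0.261 (Apln, from 0.000151).

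**Figure D2:**
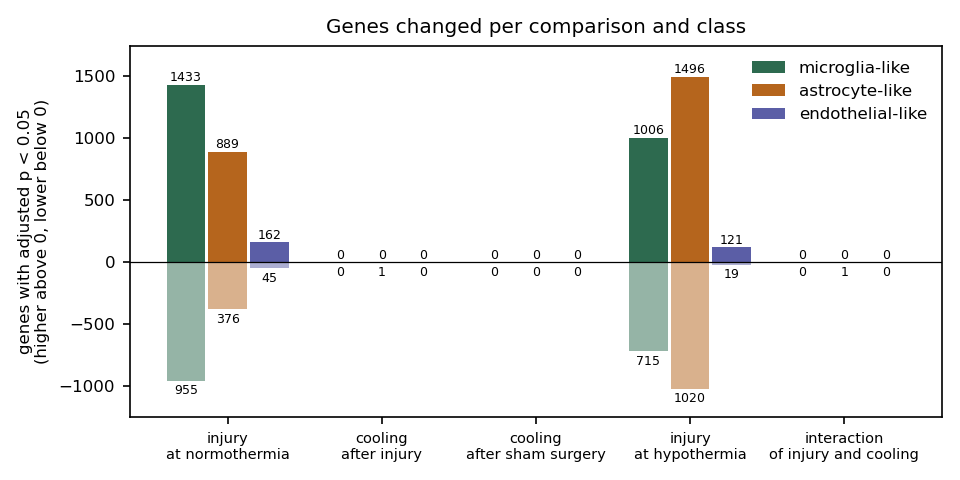
Number of genes that changed (Benjamini-Hochberg adjusted p under 0.05, edgeR) in each comparison and each of the 3 largest classes, higher and lower genes shown apart. Injury at normothermia changed 2388, 1265 and 207 genes in microglia-like, astrocyte-like and endothelial-like cells, and cooling after injury changed 1 gene in astrocyte-like cells.

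In the smaller classes 48 genes changed with injury at normothermia. Spp1 rose in border macrophage-like cells from 38.0 ± 30.5 (n = 2) to 1142 ± 180 CPM (log2 4.98, SE 0.49, adjusted p = 0.00116). Angptl4 rose in smooth muscle-like cells from 12.0 ± 4.72 to 254 ± 92.2 CPM (n = 2 injured animals, log2 4.38, SE 0.50, adjusted p = 0.0146). In pericyte-like cells 23 genes rose, led by Fabp4 (at least 20.4-fold higher at 28.1 ± 25.4 CPM) and Ecrg4 (ratio 77.4, counting interval 26 to 379). Ecrg4 is also a leading gene of choroid plexus-like cells, which stood at 0.0243% and 4.26% of the normothermic sham and injured libraries. Ttr, their first leading gene, stood at 19.0, 1.64 and 1.27 CPM in microglia-like cells of normothermic sham replicates 1, 2 and 3 and at 4141, 374 and 1200 CPM in those of the injured ones. In ependymal-like cells 12 genes rose and 11 fell: Lcn2 rose to 107 ± 137 CPM (ratio 343, counting interval 61.4 to 13600), Serpina3n from 26.2 ± 22.0 to 1125 ± 1060 CPM, and Fhod3 and Tent5a fell by log2 −1.63 and −1.56. Without sham replicate 1, 2 or 3 the count over these classes was 1, 5 and 0, and without injured replicate 1 it was 775. It was 25 at Leiden resolution 0.5, 24 with the stricter cell filter, 1406 without the low-count filter and 643 by DESeq2. Each sham replicate left out ended the calls named here in pericyte-like, ependymal-like and smooth muscle-like cells (adjusted p of 0.0905 to 0.227, 1.71e-23 to 0.227 over their alternatives), and that of Spp1 ended with only the contrast's groups (0.0724, 5.08e-30 to 0.0724).

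The second comparison, cooled against normothermic injured animals, addresses the question named in the labels, what selective brain cooling changes after trauma. In astrocyte-like cells Txnip, which encodes a protein that binds thioredoxin and restrains glucose uptake, fell from 59.3 ± 5.32 to 11.2 ± 3.09 CPM (log2 −2.40, SE 0.20, adjusted p = 0.000469), with 20.8 ± 1.89 CPM in normothermic sham animals. It was the 1 gene of 15107 past the threshold there. In pericyte-like cells 12 genes fell. Angptl4 fell from 436 ± 149 to 31.2 ± 18.6 CPM (log2 −3.90, SE 0.58, adjusted p = 0.00688), against 28.8 ± 26.4 CPM in normothermic sham animals, and Trp53inp1 from 138 ± 72.0 to 23.1 ± 3.71 CPM (log2 −2.48, SE 0.32, adjusted p = 0.00209). Angptl4 also fell in smooth muscle-like cells, from 254 ± 92.2 to 16.4 ± 11.2 CPM (n = 2 and 2, log2 −4.23, SE 0.52, adjusted p = 0.031). In neutrophil-like cells Olfm4 fell from 170 ± 55.3 to 3.92 ± 1.55 CPM (log2 −5.47, SE 0.50, adjusted p = 0.00379).

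**Figure D3:**
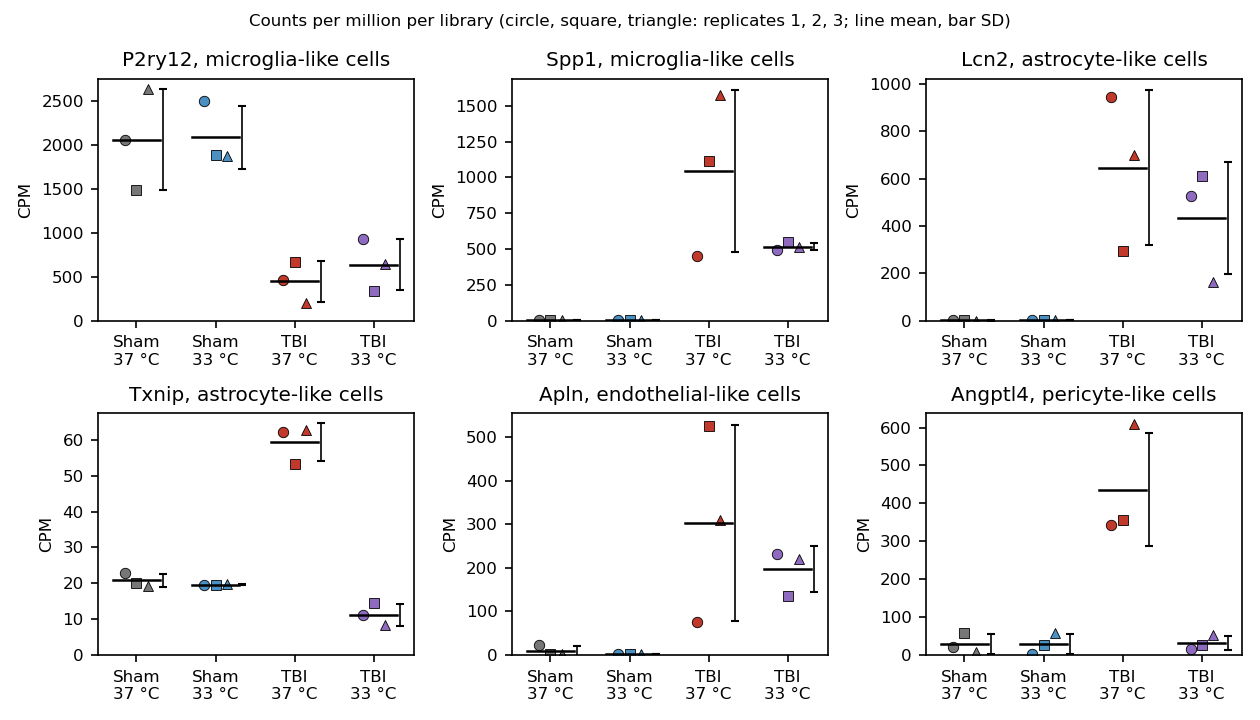
Levels of 6 genes per library in CPM, by group, in the class named over each panel (circle, square and triangle are replicates 1, 2 and 3, the line is the mean and the bar the SD). Txnip in astrocyte-like cells lay between 53.2 and 62.6 CPM in the normothermic injured libraries and between 8.24 and 14.4 CPM in the cooled ones, and Angptl4 in pericyte-like cells between 344.2 and 608 and between 15.4 and 51.7 CPM.

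The same-numbered injured animals deviated together, and in the paired model 101 astrocyte genes changed with cooling, 73 upward and 28 downward. Among the rises were the cytokine gene Il11 (6.97 to 35.5 CPM, log2 2.42, SE 0.32, adjusted p = 0.0354), Ier5l (37.9 to 172 CPM, log2 2.09, SE 0.17, adjusted p = 0.0081), Phox2a (log2 2.35), Las1l (1.86) and Eepd1 (1.86). Among the falls were Txnip (log2 −2.42, SE 0.20, adjusted p = 0.0081), Tsc22d3, a gene induced by glucocorticoids (269 to 50.3 CPM, log2 −2.24, SE 0.33, adjusted p = 0.0427), Etnppl (196 to 43.7 CPM, log2 −2.09), Nrros (−2.28) and Hif3a (−2.01). In pericyte-like cells 51 genes changed in the paired model, 20 upward, including the clock gene Dbp (72.7 to 228 CPM, log2 1.88), and 31 downward. These included Angptl4 (log2 −3.96, SE 0.40, adjusted p = 0.000115), Enpp2 (258 to 45.3 CPM, log2 −2.60) and Txnip (233 to 65.8 CPM, log2 −1.82, adjusted p = 0.00029). Enpp2 is also a leading gene of choroid plexus-like cells, which stood at 4.26% and 1.02% of the normothermic and cooled injured libraries. Their gene Ttr stood at 4141, 374 and 1200 CPM and at 1394, 0.0468 and 1.14 CPM in microglia-like cells of the same animals. The chemokine genes Ccl7 (3.73 to 172 CPM, log2 5.23, SE 0.39, adjusted p = 0.0071) and Ccl2 (39.9 to 855 CPM, log2 4.51, SE 0.49, adjusted p = 0.0475) rose in fibroblast-like cells. In oligodendrocyte precursor-like cells Hes1 rose by log2 1.58, and Fcer1g and Cyba fell by log2 −2.37 and −1.91. The paired model called 65 genes over the smaller classes, against 14 without pairing.

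Cirbp and Rbm3, RNA-binding proteins that cold induces, were not higher in cooled injured animals 24 h after injury. Cirbp stood at 105 ± 65.2 and 45.9 ± 8.85 CPM in microglia-like cells of normothermic and cooled injured animals (log2 −1.19, SE 0.41, unadjusted p = 0.0128), at 110 ± 42.2 and 61.6 ± 15.6 in astrocyte-like cells (log2 −0.84, SE 0.32, unadjusted p = 0.0222) and at 160.5 ± 78.3 and 82.4 ± 26.5 in endothelial-like cells (log2 −0.96, SE 0.39, unadjusted p = 0.0299). Rbm3 had log2 values of −1.24, −0.63 and −0.65, and neither gene passed after adjustment. In microglia-like cells no gene passed by edgeR (429 at an unadjusted p under 0.05, 4 past the threshold by DESeq2), and in endothelial-like cells none passed by edgeR (799 at an unadjusted p under 0.05, 48 by DESeq2). The smallest p-values belonged to Ms4a6b (343 ± 116 and 141 ± 41.1 CPM, log2 −1.28), Plet1os and S100a16 in microglia-like cells. In endothelial-like cells they belonged to Ucp2 (896 ± 408 and 215 ± 26.8 CPM, log2 −2.06, adjusted p = 0.214), Myrip (59.6 ± 9.16 and 21.9 ± 3.63 CPM, log2 −1.44, adjusted p = 0.214) and Chtf8 (1.68 ± 0.249 and 5.08 ± 1.13 CPM, log2 1.58, adjusted p = 0.237).

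Camera called 7 lists in microglia-like cells, 1 in astrocyte-like cells and 7 in endothelial-like cells at the preset correlation, and none held with an estimated one. In microglia-like cells the homeostatic microglia (median log2 0.41), interferon response (0.56), astrocyte homeostasis (0.36) and cholesterol synthesis lists (0.17) were higher. Their estimated-correlation adjusted p was 0.632, 0.755, 0.533 and 0.354. The cold-inducible (median log2 −0.78), A1-type (−0.24) and oxidative stress and iron lists (−0.56) were lower, with adjusted p = 0.354, adjusted p = 0.354 and adjusted p = 0.548 with an estimated correlation. The A1-type member past the threshold over the list alone was Fkbp5, a co-chaperone induced by glucocorticoids (log2 −1.75, SE 0.38), and not past it over all genes. In astrocyte-like cells the reactive astrocyte list was higher (median log2 0.48), with 3 members adjusted over the list alone, led by Cd44 (log2 1.55, SE 0.36) and S1pr3 (1.52, SE 0.38), and adjusted p = 0.734 with an estimated correlation. In endothelial-like cells the interferon response (median log2 0.37) and cholesterol synthesis lists (0.31) were higher, with adjusted p = 0.768 and adjusted p = 0.773 with an estimated correlation. The complement (−0.36), cold-inducible (−0.79), immediate early (−0.75), oxidative stress and iron (−0.34) and mitochondrially encoded lists (−0.26) were lower. Their estimated-correlation adjusted p was 0.614, 0.614, 0.768, 0.614 and 0.768. The paired model called 11, 0 and 8 lists in the 3 classes at the preset correlation.

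Neutrophil-like cells were 2.15% ± 1.60 of the normothermic and 0.508% ± 0.195 of the cooled injured libraries (log2 −2.08, unadjusted p = 0.00571, adjusted p = 0.08, exact permutation p = 0.1), which did not pass. They were lower in each pair of same-numbered animals (0.871% and 0.294%, 1.64% and 0.675%, 3.95% and 0.554%) and passed in the paired model (log2 −1.89, adjusted p = 0.0405). No class passed by edgeR on cell numbers without pairing (1 of 14 at an unadjusted p under 0.05), and 1 did without normothermic injured replicate 1. Microglia-like cells were 34.4% ± 2.91 and 34.1% ± 5.72, and astrocyte-like cells 16.7% ± 5.29 and 26.0% ± 10.5. Astrocyte-like and pericyte-like cells were higher and choroid plexus-like, fibroblast-like and border macrophage-like cells lower in each pair, without passing (paired adjusted p of 0.445 to 0.706). Endothelial-like cells with 3 or more of 16 tip cell markers, genes of the leading cells of a vessel sprout, were 31.2% ± 6.65 of the class in normothermic sham, 21.0% ± 10.3 in cooled sham, 63.6% ± 27.9 in normothermic injured and 76.7% ± 8.03 in cooled injured animals. The difference with cooling after injury was 13.1 percentage points (exact two-sided permutation p = 0.5), that with injury 32.4 points at normothermia and 55.7 points at hypothermia (p = 0.1 for both, the smallest the permutation test can give). The same count was at most 0.167% in microglia-like and at most 1.01% in astrocyte-like cells. Thinning to 3000 UMIs left out 4.91%, 4.71%, 5.86% and 2.28% of the cells of these groups, whose median counts were 6968 to 8385.5 UMIs, and without it the shares were 66.0%, 61.5%, 82.3% and 92.3%. Without thinning, normothermic injured replicate 2 (67.1%) lay below normothermic sham replicate 1 (72.4%), and with thinning the mean of the normothermic injured animals was 48.3% without replicate 3. The difference of 13.1 points was 0.963 without normothermic injured replicate 2 and 28.4 without replicate 3. Of the cells, 39.5%, 34.7%, 20.7% and 17.6% by group lay 1 marker below the limit.

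**Figure D4:**
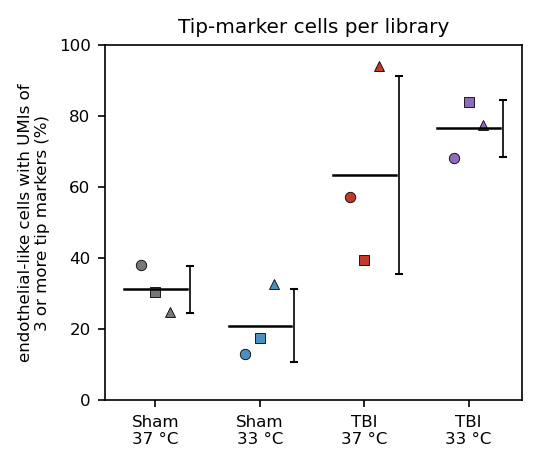
Share of endothelial-like cells with 3 or more of 16 tip cell markers per library, in percent of thinned cells, by group (circle, square and triangle are replicates 1, 2 and 3, the line is the mean and the bar the SD). Normothermic injured libraries spread from 39.4% to 94.1% and cooled injured ones from 68.2% to 84.2%.

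In cooled injured animals cluster 8, led by Il1a, Tnf and Il1b, held 30.1% ± 22.9 of microglia-like cells. Clusters 7 and 12 held 20.4% ± 28.9 and 20.2% ± 26.9. Astrocyte-like cells of cooled injured animals lay in clusters 3 (49.0% ± 24.6), 15 (19.2%) and 20 (13.1%), and endothelial-like cells in 4 (60.4% ± 15.2) and 17 (13.2%). The count of 1 astrocyte gene became 61 without cooled injured replicate 2, 391 without normothermic injured replicate 3, 11 without the low-count filter, 2 with the replicate block and 276 by DESeq2. It was 0 with only the contrast's groups, where the adjusted p of Txnip was 0.155 (3.18e-25 to 0.155 over its alternatives), and the endothelial count became 4 without normothermic injured replicate 3. With doublets kept the adjusted p of pericyte Angptl4 was 0.161 (3.29e-36 to 0.161), and without cooled injured replicate 2 or 3 that of Olfm4 was 0.0884 and 0.0786 (6.33e-18 to 0.0884). That of smooth muscle Angptl4 was 0.672 with only the contrast's groups, 0.96 without cooled injured replicate 1 and 0.0681 without replicate 3 (6.37e-19 to 0.96).

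The third comparison, cooled against normothermic sham animals, asks what cooling did without an impact. No gene passed by edgeR in microglia-like (106 at an unadjusted p under 0.05), astrocyte-like (73) or endothelial-like cells (90), and none by DESeq2 in these classes. The interferon response list was higher in microglia-like cells (median log2 1.58, adjusted p = 2.02e-11, adjusted p = 0.648 with an estimated correlation), with Ifi204 at 8.50 ± 2.76 and 24.7 ± 17.6 CPM (log2 1.57, SE 0.45, unadjusted p = 0.00425), Ifit3 at log2 2.72 (SE 0.85) and Isg15 at 1.56 (SE 0.56). The list's median level was 46.6 CPM in cooled sham replicate 1, which had Xist at 1163 CPM, and 5.31 to 12.7 CPM in the other sham libraries. Without that library its adjusted p was 0.182. The list was also higher in astrocyte-like cells (median log2 0.98, adjusted p = 4.03e-14, adjusted p = 0.103 with an estimated correlation, Usp18 at log2 1.72, SE 0.50), where without that library the adjusted p was 2.15e-08. In endothelial-like cells its median was log2 0.26 (adjusted p = 0.0136, adjusted p = 0.853 with an estimated correlation), and the adjusted p was 0.765 without that library and 0.0705 without normothermic sham replicate 1. The antigen presentation list was higher in microglia-like cells (median log2 0.24, adjusted p = 0.00457, adjusted p = 0.648 with an estimated correlation), and H2-Aa, at log2 3.43 (SE 1.02), did not pass.

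In astrocyte-like cells the antigen presentation, reactive astrocyte, A1-type, inflammasome, complement and blood-brain barrier lists were also higher in cooled sham animals, with medians of log2 0.20 to 0.52. The estimated correlation gave adjusted p of 0.103, 0.0917, 0.349, 0.154, 0.731 and 0.4. The smallest p-values in astrocyte-like cells belonged to the transcription factor gene Six3 (1.46 ± 0.191 and 5.64 ± 2.38 CPM, log2 2.01), Crym (2.83 ± 1.79 and 52.8 ± 56.7 CPM, log2 4.22) and Six3os1 (log2 2.60). In endothelial-like cells they belonged to Pxdn (log2 −2.20), Cyp26b1 (3.04) and Bloc1s1 (0.77), and none had an adjusted p below 1. Cirbp and Rbm3 stood at 54.1 ± 13.5 and 61.4 ± 11.5 CPM and at 151 ± 36.2 and 148 ± 71.1 CPM in microglia-like cells (log2 0.20 and −0.02). No cell class changed in share by edgeR (1 of 14 at an unadjusted p under 0.05, choroid plexus-like cells at 0.0243% ± 0.0211 and 1.09% ± 0.970, log2 5.40, unadjusted p = 0.0389). Its adjusted p of 0.417 was the smallest, shared with neutrophil-like cells at 0.0496% ± 0.0227 and 0.131% ± 0.0251 (unadjusted p = 0.0596). The list counts of 2, 7 and 1 moved by over 1.5 times to 1, 1, 4, 5 and 4 in microglia-like cells without cooled sham replicate 1, 2 and 3 and normothermic sham replicate 1 and 2, and to 4 in astrocyte-like cells without normothermic sham replicate 3. In endothelial-like cells they moved to 3, 2 and 5 without cooled sham replicates 1, 2 and 3 and to 6, 7 and 5 without normothermic ones. Over the smaller classes no gene passed by edgeR and 2 by DESeq2, 57 without the low-count filter and 9 without cooled sham replicate 2, and in pericyte-like cells 134 genes had an unadjusted p under 0.05.

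The fourth comparison set cooled injured against cooled sham animals. Microglia-like cells changed in 1721 genes, 1006 upward and 715 downward. Adam8 rose from 0.389 ± 0.339 to 155 ± 74.5 CPM (log2 8.15, SE 0.62, adjusted p = 5.24e-05), Spp1 from 3.75 ± 2.84 to 517 ± 26.3 CPM (log2 7.40, SE 0.77, adjusted p = 0.000589) and the scavenger receptor gene Msr1 from 2.83 ± 1.35 to 297 ± 192 CPM (log2 6.64, SE 0.77, adjusted p = 0.000905). Il1rn and Ch25h rose to 33.9 ± 26.7 and 30.9 ± 3.22 CPM (log2 6.54 and 6.41). Pdcd4, an inhibitor of translation, fell from 72.9 ± 14.1 to 18.7 ± 6.85 CPM (log2 −1.95, SE 0.33, adjusted p = 0.00552), and Upk1b, Tnfrsf17, Il7r and Crybb1 fell by log2 −2.64, −2.77, −1.99 and −2.02. Of the disease-associated list 6 of 15 rose (8 adjusted over the list alone), of the cytokines 9 of 16 (10), of hypoxia and glycolysis 8 of 17 (11), of cholesterol synthesis 6 of 17 (9, with Sqle at log2 1.38, SE 0.27) and of extracellular matrix 5 of 10 (7). With an estimated correlation these gave adjusted p of 0.162, 0.162, 0.419, 0.0734 and 0.162. The reactive astrocyte list (8 of 11 and 9, with Cd44 at log2 4.93, SE 0.53, and Vim at 4.02, SE 0.48) held at 0.00982, and of 12 homeostatic genes 2 fell (5), Siglech and P2ry12 (adjusted p = 0.504 with an estimated correlation).

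Astrocyte-like cells changed in 2516 genes, 1496 upward and 1020 downward. Tgm1 reached 73.1 ± 36.4 CPM (ratio 2600, counting interval 466 to 103000, adjusted p = 1.99e-05), Fosl1 88.5 ± 71.6 CPM and Phox2a, a transcription factor of neurons, 54.5 ± 52.8 CPM. These were at least 1170-fold and 721-fold higher than in cooled sham animals, and Steap4 was at least 232-fold higher. Unc13c, Pdzph1, Nat8f5, Fam181a and Fn3k fell by log2 −2.89, −2.69, −2.53, −2.40 and −2.23. Each of 13 reactive astrocyte genes and of 12 A2-type genes rose (13 and 12 adjusted over the list alone), with S1pr3 at log2 6.39 (SE 0.51) and Ptx3 at 7.99 (SE 0.68). Both lists held with an estimated correlation (0.00338 and 0.00473). Of 15 interferon response genes 6 rose (9), of 15 cytokines 10 (13), of 11 A1-type genes 7 (9) and of 13 astrocyte homeostasis genes 3 fell (5): the connexin gene Gja1 (log2 −1.02, SE 0.26), Slc7a10 (−1.02, SE 0.26) and glutamine synthetase, Glul (−0.97, SE 0.30). The estimated correlation gave these adjusted p of 0.286, 0.066, 0.203 and 0.286. Endothelial-like cells changed in 140 genes, 121 upward and 19 downward. Angpt2 rose by log2 4.21 (SE 0.29, adjusted p = 0.000118), Apln from 1.75 ± 0.472 to 197 ± 52.5 CPM (log2 6.84, adjusted p = 0.0332) and the receptor gene Kit from 1.40 ± 1.47 to 79.5 ± 62.1 CPM (log2 6.47, adjusted p = 0.0412). The guidance ligand gene Sema3c fell from 609 ± 53.9 to 214 ± 26.3 CPM (log2 −1.51, adjusted p = 0.0391). Of 16 tip cell genes 5 rose (15 adjusted over the list alone, adjusted p = 0.198 with an estimated correlation). Camera called 12, 15 and 15 lists in the 3 classes at the preset correlation, of which 1, 2 and 0 held with an estimated one.

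In pericyte-like cells 21 genes rose, led by Ccl2 (ratio 290, counting interval 51.7 to 11500) and Il11 (ratio 189, counting interval 52 to 1560), and in border macrophage-like cells Spp1 rose to 915 ± 146 CPM (log2 6.71, adjusted p = 0.00032). Monocyte/macrophage-like cells rose from 0.0921% ± 0.0271 to 1.47% ± 0.123 (log2 4.05, adjusted p = 0.0033, exact permutation p = 0.1), and neutrophil-like cells stood at 0.131% ± 0.0251 and 0.508% ± 0.195 (log2 1.90, adjusted p = 0.0972). The microglia count was 401, 689 and 690 without cooled sham replicates 1, 2 and 3 and 744 and 679 without cooled injured replicates 2 and 3. The astrocyte count was 1302, 1004 and 1316 without cooled sham replicates 1, 2 and 3 and 1460 without cooled injured replicate 3. The endothelial count was 1, 2 and 1 without the sham and 27, 57 and 2 without the injured replicates 1, 2 and 3, 892 with only the contrast's groups and 837 by DESeq2. In microglia-like cells the calls of P2ry12 and Siglech ended without cooled sham replicate 1, 2 or 3 or cooled injured replicate 2 or 3, and that of Crybb1 without any of the 6 libraries. Those of Il7r and Tnfrsf17 without sham replicate 1 or 2 or injured replicate 3 (Tnfrsf17 also without injured replicate 2) and that of Upk1b without sham replicate 1 (2.48e-05 to 0.0991 over their alternatives). In astrocyte-like cells the calls of Fam181a and Slc7a10 ended without sham replicate 2 or injured replicate 2 or 3, that of Gja1 without sham replicate 2 or 3 or injured replicate 1 or 3 and that of Glul without any of the 6 (0.000416 to 0.12). Those of Apln and Sema3c ended without any of the 6, that of Kit without any but injured replicate 1 (2.15e-07 to 0.249), and those of Ccl2 and Il11 in pericyte-like cells without sham replicate 1, 2 or 3 or injured replicate 3 (1.4e-46 to 0.393).

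The fifth comparison, the interaction, asks whether the injury effect differed between cooled and normothermic animals. Txnip in astrocyte-like cells was the 1 gene that passed in the 3 largest classes (log2 −2.30, SE 0.27, adjusted p = 0.025): it stood at 20.8 ± 1.89 and 59.3 ± 5.32 CPM in normothermic sham and injured animals and at 19.5 ± 0.157 and 11.2 ± 3.09 CPM in cooled ones. No gene passed by edgeR in microglia-like cells (243 at an unadjusted p under 0.05, 1 by DESeq2) or endothelial-like cells (435, and 3 by DESeq2), and 854 had an unadjusted p under 0.05 in astrocyte-like cells. The endothelial genes of smallest p were Myrip (log2 −1.77), Pcdh12 (4.15, with 8.27 ± 2.53 and 1.36 ± 0.681 CPM in normothermic sham and injured and 2.86 ± 0.805 and 8.26 ± 4.67 CPM in cooled sham and injured animals) and Ucp2 (−2.04). The share of neutrophil-like cells passed as well (log2 −3.49, adjusted p = 0.0388), with means of 0.0496% and 2.15% at normothermia and 0.131% and 0.508% at hypothermia.

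Of the lists in the interaction, interferon response (median log2 −1.53), antigen presentation (−0.65), A1-type (−0.99), complement (−0.76) and astrocyte homeostasis (−0.25) were lower in astrocyte-like cells, with Ifit1 at log2 −2.70 (SE 0.94) and H2-D1 at −1.40 (SE 0.47). With an estimated correlation they gave adjusted p of 0.389, 0.389, 0.389, 0.824 and 0.389. In microglia-like cells the homeostatic microglia, astrocyte homeostasis and cholesterol synthesis lists were higher and the antigen presentation, A1-type, cold-inducible, immediate early, and oxidative stress and iron lists lower. Estimated correlations gave adjusted p = 0.157 for the A1-type and cold-inducible lists, adjusted p = 0.325 for cholesterol synthesis and adjusted p = 0.843 for the others. In endothelial-like cells the complement, cold-inducible, immediate early, oxidative stress and iron, and mitochondrially encoded lists were lower, each with adjusted p = 0.717 with an estimated correlation.

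The paired model gave Txnip an adjusted p of 0.208 in the interaction, and the replicate block 0.0697. Leaving out cooled sham replicate 1, 2 and 3 gave 0.136, 0.127 and 0.133, normothermic sham replicate 1, 2 and 3 0.0895, 0.173 and 0.167, cooled injured replicate 1 0.131 and normothermic injured replicate 1 and 2 0.0817 and 0.0629 (6.75e-10 to 0.208 over its alternatives). The count of 1 share became 0 with doublets kept, with TMM over classes and without cooled sham replicate 1, 2 or 3, normothermic sham replicate 1 or 3, cooled injured replicate 2 or 3 or normothermic injured replicate 2 or 3, and 2 without cooled injured replicate 1.

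On GRCm38 with GENCODE M21, Txnip (ENSMUSG00000038393.14) lies on chromosome 3 from 96557957 to 96561883 on the plus strand, Angptl4 (ENSMUSG00000002289.16) on chromosome 17 from 33773750 to 33781830 on the minus strand, and Spp1 (ENSMUSG00000029304.14) on chromosome 5 from 104435118 to 104441050 on the plus strand. Angpt2 (ENSMUSG00000031465.6) lies on chromosome 8 from 18690263 to 18741562 and Apln (ENSMUSG00000037010.7) on chromosome X from 48025146 to 48034853, both on the minus strand. Cirbp (ENSMUSG00000045193.13) lies on chromosome 10 from 80165985 to 80172786 on the plus strand and Rbm3 (ENSMUSG00000031167.16) on chromosome X from 8138975 to 8145880 on the minus strand.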

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

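The 3 tests of the interferon genes and all counts over other splits of the animals were chosen only after the results were seen, as were the 3 patterns themselves and the list of glucocorticoid-induced genes, whereas the predictions of the other tests were written before those tests were run.

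The effect of injury on Txnip in astrocyte-like cells differed between cooled and normothermic animals (interaction log2 −2.30, SE 0.27, adjusted p = 0.025), which drew attention as a tested difference between groups. The share of neutrophil-like cells did so too (interaction log2 −3.49, adjusted p = 0.0388). Clusters 37, 38 and 39, which have no name and are left out of the comparisons, stood out because their highest share in an injured library lay above that in every sham library. Cluster 37, with Sfn, Cd109 and Cxcl10 among its leading genes, made up 3.42% of normothermic injured replicate 3 and at most 0.0365% of a sham library. Cluster 38, with Npy, Frzb, Apod and Fabp7, made up 3.27% of normothermic injured replicate 1 and was absent from the other libraries. Cluster 39, with markers of T, NK and B cells, made up 0.72% of normothermic injured replicate 2 and at most 0.22% of a sham library.

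In cooled injured animals 13 genes were lower and 2 higher at an unadjusted p under 0.05 in 6 or more of 12 classes (Cirbp in 10, Enpp2, Klf9 and Ucp2 in 8), but 13 lower and 37 higher without normothermic injured replicate 3, 37 and 15 without replicate 1, 22 and 4 without replicate 2, 20 and 8 without cooled injured replicate 1, 4 and 1 without cooled injured replicate 3, 65 and 22 without the low-count filter, 7 and 2 with only the contrast's groups and 22 and 17 in the paired model. RNA free in the cell suspension could lower a gene everywhere. For 10 of the 13 the difference in some class exceeded 5 times the lowest class level. Ucp2 had 896 and 215 CPM in endothelial-like and 26.0 in neuroblast-like cells. Such a gap argues against free RNA in that class alone. It stays open elsewhere, and for Cirbp (3.36 times), Enpp2 (3.67) and Eci2 (4.33). Normothermic injured replicate 3 alone might carry the pattern: without it 5 of the 13 genes remained, which leaves this open because that lies between the 0 genes predicted if it were the cause and the more than 6 predicted if not. Lower glucocorticoid signalling, a hypothesis prompted by Fkbp5 and Tsc22d3, could also lower them, but a list of other glucocorticoid-induced genes was lower with an estimated correlation in 1 of 12 classes, which leaves it open because 7 were lower at the preset correlation, and a list of FoxO and PPAR targets, drawn up after its members' values were seen, was lower with an estimated correlation in 8 of 12 and decides nothing. Of the 10 unpaired splits of the injured animals 6 had as many genes in 1 direction, with 13 for the real split and 209 for the highest other, and the paired model over 13 classes gave 25 lower and 20 higher genes, against 5 and 4, 17 and 13 (12 classes) and 6 and 24 with pair 1, 2 and 3 swapped, and 4 swaps are too few to tell the grouping from chance.

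The interferon response list was higher in cooled than in normothermic sham animals at the preset correlation, with adjusted p = 0.648 in microglia-like, adjusted p = 0.103 in astrocyte-like and adjusted p = 0.853 in endothelial-like cells with an estimated correlation. A single animal might account for it: without cooled sham replicate 1 the adjusted p was 0.182 in microglia-like cells, which fits that explanation, and 2.15e-08 in astrocyte-like cells, which argues against it there. That library, labelled male, was the 1 library with Xist over 100 CPM and under 10 UMIs of 4 Y-linked genes, so the sex of the animal could matter, which stays open because 1 library had that pattern. No explanation through cooling itself was tested.

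Cxcl3, Il1r2 and Saa3 were high in microglia-like cells of normothermic injured animals, most in replicate 3. Neutrophils among these cells could bring in such RNA, and the level expected from S100a8 or S100a9 was at most 0.205 of the measured level over 3 genes and 3 libraries. That highest ratio, Il1r2 in replicate 2 at 0.896 CPM, missed the limit of 0.2 set beforehand, so neutrophils stay open. Those low in S100a8 and S100a9, which lead their cluster, would be missed. Replicate 3 alone might carry the pattern, but without it 3 of 3 genes kept an adjusted p under 0.05 (0.0119, 0.0367 and 0.00613), with lower log2 changes of 8.13, 5.73 and 4.50 against 10.79, 9.05 and 7.72. No biological explanation was tested.

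With 3 animals per group there are 10 splits, so no split count can fall under 1 in 10, and it can only be said how the real value stands beside the highest other. For genes changed with injury at normothermia these were 2388 and 0 in microglia-like, 1265 and 0 in astrocyte-like and 207 and 0 in endothelial-like cells, and at hypothermia 1721 and 0, 2516 and 0, and 140 and 0, with 1 split of 10 as large in each. For cooling after injury they were 0 and 2 (10 of 10 splits as large), 1 and 1901 (3 of 10) and 0 and 37 (10 of 10), and for cooling after sham surgery 0 and 0 in each class (10 of 10). The split with 1901 astrocyte genes set cooled replicate 1 and normothermic replicates 1 and 2 against the rest, which points to a structure of the samples other than temperature. Over 4 swaps of pairs the paired model gave 0 and 0 in microglia-like (4 of 4), 101 and 0 in astrocyte-like (1 of 4) and 0 and 0 in endothelial-like cells (4 of 4). In the smaller classes with 3 animals in each group of a comparison, fewer than those counted in the report, the real and highest other counts were 46 and 1 (1 of 10), 13 and 439 (3 of 10), 0 and 1 (10 of 10) and 21 and 1 (1 of 10) for injury at normothermia, cooling after injury, cooling after sham surgery and injury at hypothermia. For shares they were 2 and 0 (1 of 10), 0 and 1 (10 of 10), 0 and 1 (10 of 10) and 1 and 1 (2 of 10).

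For gene lists in the same 4 comparisons the real and highest other counts were 12 and 13 (2 of 10), 7 and 10 (7 of 10), 2 and 7 (10 of 10) and 12 and 10 (1 of 10) in microglia-like cells. They were 17 and 15 (1 of 10), 1 and 12 (10 of 10), 7 and 9 (3 of 10) and 15 and 13 (1 of 10) in astrocyte-like cells, and 13 and 16 (3 of 10), 7 and 11 (4 of 10), 1 and 10 (10 of 10) and 15 and 11 (1 of 10) in endothelial-like cells. For the interaction, with 50 splits, genes gave 0 and 1 (50 of 50), 1 and 192 (7 of 50) and 0 and 72 (50 of 50) in microglia-like, astrocyte-like and endothelial-like cells, lists 8 and 12 (22 of 50), 5 and 12 (35 of 50) and 5 and 12 (39 of 50), and shares 1 and 1 (3 of 50). The counts of 1 gene and 1 share in the interaction are therefore no larger than random groupings gave. The sizes of the changes were not compared.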

How the results depend on the processing

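The paired model was chosen only after the data were seen, and the other alternatives were planned. No call of a named gene reversed direction under any alternative. Of all their values 10709 kept their side of the threshold, 638 fell short of it and 329 passed it. The cause was not tested for the changes that follow, except that leaving out an animal or group lowers the number of samples. With only the groups of the contrast, genes changed with injury at normothermia were 716 in microglia-like, 267 in astrocyte-like and 0 in endothelial-like cells, with cooling after injury 0 in astrocyte-like cells and 4 in the smaller classes, and with injury at hypothermia 892 in endothelial-like cells and 160 in the smaller classes. By DESeq2 they were 2194 (astrocyte-like), 1053 (endothelial-like) and 643 (smaller classes) with injury at normothermia, 4, 276, 48 and 72 (microglia-like, astrocyte-like, endothelial-like, smaller) with cooling after injury, 2 (smaller) with cooling after sham surgery, 837 (endothelial-like) and 170 (smaller) with injury at hypothermia, and 1, 2 and 3 (microglia-like, astrocyte-like, endothelial-like) in the interaction. Without the low-count filter they were 393 (endothelial-like) and 1406 (smaller) with injury at normothermia, 11, 1 and 636 (astrocyte-like, endothelial-like, smaller) with cooling after injury, 57 (smaller) with cooling after sham surgery, 234 (endothelial-like) and 739 (smaller) with injury at hypothermia and 122 (smaller) in the interaction. With the replicate block they were 72 in endothelial-like cells with injury at normothermia, 2 in astrocyte-like cells and 30 in the smaller classes with cooling after injury, 36 in the smaller classes with injury at hypothermia, and 0 in astrocyte-like cells and 1 in the smaller classes in the interaction. The paired model gave 101 in astrocyte-like cells and 65 in the smaller classes with cooling after injury, 0 in astrocyte-like cells and 1 in the smaller classes in the interaction, and 11 lists in microglia-like and 0 in astrocyte-like cells with cooling after injury. It gave 6 for 7 lists in astrocyte-like cells with cooling after sham surgery, 8 for 7 in endothelial-like cells with cooling after injury, 6 for 5 in astrocyte-like cells in the interaction, and 2 higher and 6 lower for 3 and 5 in microglia-like cells in the interaction, and moved no other count by over 1.5 times beyond those given here. In the smaller classes 25 genes changed with injury at normothermia at Leiden resolution 0.5 and 24 with the stricter cell filter, 9 with cooling after injury with doublets kept, and 12 with injury at hypothermia with RLE size factors. Shares changed in 4 classes with injury at normothermia with doublets kept and in 4 at Leiden resolution 0.5, in 1 (neutrophil-like) with cooling after injury in the paired model, and in 0 in the interaction with doublets kept and with TMM over the classes. With an estimated correlation the lists called over the 5 comparisons were 1, 0, 0, 1 and 0 in microglia-like, 7, 0, 0, 2 and 0 in astrocyte-like and 0 throughout in endothelial-like cells, where the replicate block gave 2 and the paired model 3 with cooling after sham surgery.

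Leaving out 1 animal at a time gave these lowest and highest counts for injury at normothermia, cooling after injury, cooling after sham surgery, injury at hypothermia and the interaction. Genes in microglia-like cells: 645 to 3231, 0 to 0, 0 to 0, 401 to 1462 and 0 to 0. Genes in astrocyte-like cells: 228 to 1894, 1 to 391, 0 to 0, 1004 to 1830 and 0 to 2. Genes in endothelial-like cells: 1 to 768, 0 to 4, 0 to 0, 1 to 57 and 0 to 0. Genes in the smaller classes: 0 to 775, 3 to 187, 0 to 9, 3 to 36 and 0 to 6. Shares: 2 to 3, 0 to 1, 0 to 0, 1 to 1 and 0 to 2. Lists in microglia-like cells: 10 to 14, 5 to 12, 1 to 5, 10 to 15 and 4 to 11. Lists in astrocyte-like cells: 16 to 18, 1 to 9, 4 to 9, 12 to 15 and 4 to 8. Lists in endothelial-like cells: 12 to 15, 3 to 11, 2 to 7, 12 to 16 and 2 to 9. The 1 higher list in astrocyte-like cells with cooling after injury became 1 higher and 8 lower without normothermic injured replicate 1 and 1 lower without replicate 2. The difference in tip-marker share with cooling after injury was 0.963 to 28.4 points. DESeq2 gave no adjusted p for Fabp4, Ecrg4 and Trp53inp1 in pericyte-like cells. The UMI part of the stricter cell filter removed no cell, since the deposited cells had more. Cooled sham replicate 3, with 912 cells, limits depth in that group.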

Other observations

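The tests in the paired model below were chosen only after the results were seen.

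Txnip was lower in cooled injured animals in the paired model in several classes beside astrocyte-like and pericyte-like cells without passing: log2 −1.46 (SE 0.36, adjusted p = 0.46) in endothelial-like cells, −2.40 (SE 0.48, adjusted p = 0.119) in oligodendrocyte precursor-like cells and −1.28 (SE 0.29, adjusted p = 0.302) in smooth muscle-like cells. In microglia-like cells it stood at log2 −0.03 (SE 0.16, adjusted p = 0.997).

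Ttr stood at 0.465, 1013 and 742 CPM in microglia-like cells of cooled sham replicates 1, 2 and 3. Microglia cluster 14 drew 95.9% of its cells from normothermic injured replicate 3, and endothelial cluster 17 drew 58.2% from it.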
